A study of Enterococcus faecalis OG1RF with 6 samples.

How the data were processed

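RNA was sequenced from 48 h biofilms of Enterococcus faecalis OG1RF, a laboratory strain of a gut bacterium, grown alone (3 mono-species samples) or with the yeast Candida albicans SC5314 (3 dual-species samples). Per the labels, biofilms grew in 6-well plates at 37 °C in 5% CO2, in brain heart infusion broth with 20 mM glucose that was refreshed at 24 h. Mono-species wells received 5 mL of an E. faecalis suspension at an OD600 of 0.5, and dual-species wells received 2.5 mL of it and 2.5 mL of a C. albicans suspension at an OD600 of 0.3. The volume of E. faecalis suspension therefore differed between the groups along with the presence of the yeast. Wells were pooled 3 to a sample, and stranded total RNA libraries were made with removal of ribosomal RNA. The labels do not say whether the samples of a group came from separate cultures, so each p-value measures the spread between these samples, which may be partly technical.

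The deposited tables give 1 signal value per gene and library, with a locus tag, a gene symbol where there is one, and a product name. The authors' notes name HISAT2, Subread, featureCounts and edgeR; their versions, the genome build, the counting options and the handling of reads that match several genes or come from C. albicans are not given in the sources used here. The deposited signal values were CPM values (read counts relative to the library total) further scaled by a composition factor per library: the columns summed to between 860662 and 1.19e+06, and the 6 implied factors lay between 0.838 and 1.16. In every library 100% of the values were whole multiples of the value of 1 read, within 0.01 read, so read numbers could be worked out. These gave 15143323, 14663944 and 16654998 reads for mono-species samples 1 to 3 and 25480041, 31346507 and 30520943 for dual-species samples 1 to 3, so depth differed along with group. All 2564 genes had, at the median depth, at least 10 reads in at least 3 libraries and at least 15 reads in total, so none was left out. In 58 genes some library held fewer than 10 reads, and the lowest read number was 0. Of the genes, 1079 had a symbol, 513 had a hypothetical, uncharacterized or DUF product, and 0 were annotated as ribosomal or transfer RNA, so the share of reads in such RNA could not be measured. With no genome sequence at hand, gene neighbours were taken from the order of locus tags.

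Groups were compared with limma 3.58.1 in R 4.3.3: a linear model of log2(signal + 1) in the 6 samples with group as its term, an empirical Bayes step with a mean-variance trend (limma-trend), two-sided p-values and Benjamini-Hochberg adjustment over the 2564 genes. A gene was called at an adjusted p under 0.05, and counted as at least 2-fold when its log2 change was also at least 1 in size. Fold changes are on the log2(signal + 1) scale, which understates changes of genes with low signal. A positive log2 change means higher signal in the dual-species biofilms. A count model such as edgeR's was the first choice and was not used as the main test, because the tables held scaled values; limma-trend had been set as the test for that case. Limma-voom on the worked-out reads called 1701 genes, of which 1685 were shared with the 1696 of limma-trend.

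Gene lists were tested with limma's camera on the log2(signal + 1) values, with a preset correlation of 0.01 between genes, for lists with at least 5 members and with adjustment over the lists. Camera with the correlation estimated per list and limma's fry were run beside it. Members of a list are counted as called over all genes and as called when adjusted over the list alone. The 39 lists were drawn up from symbols, product names and locus tags; 37 were tested. The list of bacteriocins was left out as void because its only member, OG1RF_11095, could not be tied to a bacteriocin by the tables (log2 change -0.09, limma adjusted p = 0.70). The list of ribosomal and transfer RNA was left out because its 4 members, dus, tgt, truA and truA2, encode enzymes that modify transfer RNA (log2 changes -1.06, -0.21, 0.23 and 1.28).

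Named genes were chosen by a rule. It took the 10 highest and 10 lowest log2 changes among called genes with a mean signal of at least 20, no overlap between the groups and an informative product. It added the ebp pilus and fsr genes, ace, sodA, ahpC and katA whatever their p, up to 4 members with the lowest adjusted p from each list that camera called, and the 3 genes with the highest mean signal. The genes efaA, atlA and entV of that rule were not found under those symbols and are not reported here. This gave 54 genes; all other genes named as list examples were chosen after their values were seen. The test, its thresholds, the lists, the rule for names and the first alternatives were chosen before the data were examined.

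The first alternatives were median-ratio, upper-quartile and plain library-total scaling, no low-value filter, a filter of at least 10 CPM in at least 3 libraries, the replicate number as a block, a robust empirical Bayes step, a stricter adjusted p of 0.01 and leaving out each of the 6 libraries in turn. Added after seeing the data were pseudocounts of 0.1 and 5, limma-voom, thinning of every library to the shallowest, limma's treat against a 2-fold change, and lists without members whose product differs from the list's name. The call procedure was tested on simulated data with 2564 genes and 3 libraries per group. Every simulated gene had the same relative spread, the median of genes with a mean signal of at least 20, averaged over the groups. Changes were given to 200 genes, as many up as down, and the scaling was known. The procedure called 100% of 100 genes with a 2-fold change and 78% of 100 genes with a 1.5-fold change, together with 10 unchanged genes. With most genes called here and the scaling open, these shares may not hold for these data. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 served for loading and plotting.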

Results

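RNA levels of 2564 E. faecalis genes were measured in 6 biofilm samples, 3 mono-species and 3 dual-species, with 14663944 to 16654998 reads assigned to genes in mono-species and 25480041 to 31346507 in dual-species libraries. The comparison asked how the presence of C. albicans went along with the RNA levels of E. faecalis in a 48 h biofilm; C. albicans transcripts were not in the tables. Spearman correlations across genes, which are not independent replicates, were 0.989 to 0.996 between mono-species libraries, 0.988 to 0.994 between dual-species libraries and 0.912 to 0.929 between the groups. The first principal component held 87.1% of the variance and separated the groups.

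In dual-species biofilms, genes for sugar uptake and glycerol use were among those with the highest increases. The signal of OG1RF_10752, a membrane component of a lactose/cellobiose phosphotransferase system (PTS), was 14.3 ± 1.59 in mono-species and 917 ± 177 in dual-species biofilms (mean ± SD, n = 3 each), a log2 change of 5.89. Glycerol dehydrogenase gldA rose from 75.2 ± 4.42 to 1789 ± 110 (log2 change 4.55), and ribokinase rbsK from 15.5 ± 1.70 to 448 ± 121 (4.74). Most genes for peptide uptake, the protein quality regulator ctsR and the Clp ATPase clpC, and most ribosomal protein genes fell. The signal of clpC fell from 2488 ± 190 to 413 ± 51.9 (log2 change -2.59), and that of opp2D, in a block of peptide transporter genes, from 315 ± 64.1 to 32.4 ± 3.86 (-3.23).

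Limma called 1696 of the 2564 genes (66.1%), 855 higher and 841 lower in dual-species biofilms, and 731 of them at least 2-fold (408 higher, 323 lower; 332 and 408 with upper-quartile scaling, 253 and 586 with library totals). When the change itself was tested against 2-fold with limma's treat, 322 genes passed (216 higher, 106 lower). The values of the groups did not overlap in 1811 genes (70.6%, where chance gives 10%). The split into higher and lower depended on the scaling: the median log2 change of all genes was -0.04 with the authors' scaling, -0.17 with upper-quartile scaling (715 higher, 970 lower) and -0.38 with plain library totals (540 higher, 1217 lower). Changes below are those with the authors' scaling, and genes or lists whose direction turns under another scaling are named as such.

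**Figure D1:**
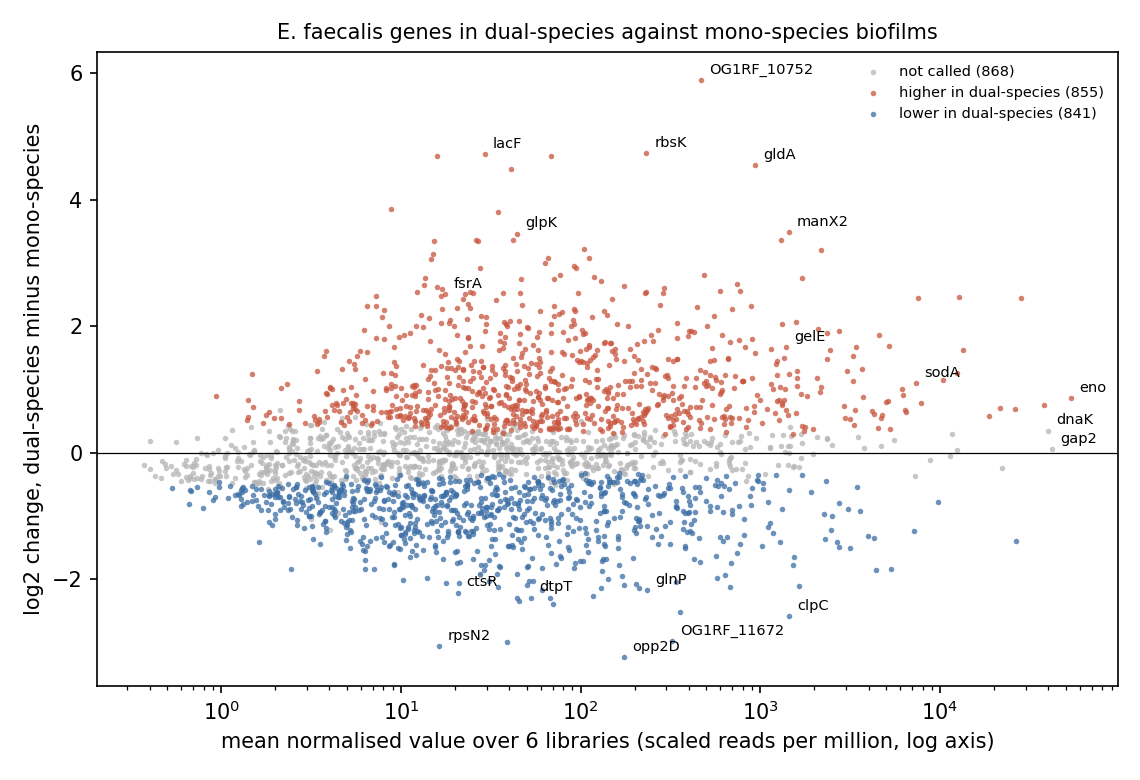
Log2 change of each of 2564 genes, dual-species minus mono-species (vertical axis), against its mean signal over the 6 libraries (horizontal log axis, scaled CPM). Red points are the 855 genes called higher, blue points the 841 called lower and grey points the 868 not called; with plain library totals the split was 540 higher and 1217 lower.

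Sugar uptake genes went both up and down. Of 87 PTS genes, which take up and phosphorylate sugars, 28 rose and 23 fell (28 and 21 adjusted over the list alone). The list was not called by camera (camera adjusted p = 0.43). Its median log2 change was 0.03 and turned to -0.07 with upper-quartile scaling. With library totals it turned to -0.26, and 20 genes were called higher and 34 lower. Beside OG1RF_10752, the block OG1RF_10745 to OG1RF_10753 held lacF, a lactose/cellobiose component that rose from 1.23 ± 0.595 to 57.2 ± 10.9 (log2 change 4.73), and the 6-phospho-beta-glucosidase bglA2, which rose from 7.94 ± 6.75 to 76.2 ± 10.4 (3.36). In that block 7 of 8 genes rose. In the mannose PTS block OG1RF_10018 to OG1RF_10023, 5 of 6 genes rose, among them manX2, from 235 ± 10.8 to 2644 ± 247 (3.48), OG1RF_10021 (3.21), manY (2.80) and manX (2.33). OG1RF_12477, called an ascorbate PTS component, rose from 2.48 ± 0.461 to 79.6 ± 27.3 (4.49). Close copies of PTS genes are less certain, since the handling of reads that match several genes is not given.

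Glycerol use was one of the lists called by camera, higher in dual-species biofilms. Of its 14 genes, 10 rose and 2 fell, the same numbers adjusted over the list alone, with a median log2 change of 1.45 (camera adjusted p = 0.0073; adjusted p = 0.40 with an estimated correlation). Glycerol kinase glpK rose from 6.47 ± 1.47 to 81.9 ± 19.7 (log2 change 3.47), glycerol-3-phosphate oxidase glpO rose by 2.04, and the dihydroxyacetone kinase genes dhaK and OG1RF_11149 by 2.01 and 1.76. The list also held 4 genes that its wording took in, the diacylglycerol kinase genes OG1RF_10085 (2.78), dgkA (0.57), OG1RF_12016 (0.65) and OG1RF_12032 (-1.25), which phosphorylate a membrane lipid. Without them, 7 of 10 genes rose and 1 fell (camera adjusted p = 0.0085; adjusted p = 0.54 with an estimated correlation), an alternative added after the values were seen.

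Central carbon metabolism moved in parts. Of 14 genes for pyruvate use and fermentation, 10 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.078; 0.042 with library totals and 0.049 without dual-species sample 3). The pyruvate dehydrogenase genes pdhA and pdhB rose by 2.56 and 2.07 on the log2 scale, and alsS and budA, which turn pyruvate into acetoin, by 2.17 and 1.93, while of the lactate dehydrogenase genes ldh1 rose by 0.54 (not called with library totals) and ldh2 fell by 0.83. Another of the list's genes that fell, nrdG (-0.78), has the product name of a pyruvate formate-lyase activating enzyme but the symbol of an activator of ribonucleotide reductase, so it may not belong there. Of 15 glycolysis genes, 8 rose and 3 fell, the same adjusted over the list alone, and the list's median log2 change of 0.37 turned to -0.01 with library totals, where 4 were called higher and 6 lower (camera adjusted p = 0.33). The aldolase fbaB rose by 2.46 and pgi by 1.33. Enolase, eno, had the highest mean signal of all genes and rose from 37927 ± 1877 to 69361 ± 6708 (log2 change 0.87). The glyceraldehyde-3-phosphate dehydrogenase gap2 had a signal of 41244 ± 1566 in mono-species and 42781 ± 1257 in dual-species biofilms (log2 change 0.05, limma adjusted p = 0.75); with library totals its direction turned, to -0.33 (adjusted p = 0.045).

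Protein synthesis genes went in opposite directions. Of 62 ribosomal protein genes, 40 fell and 5 rose, the same adjusted over the list alone, with a median log2 change of -0.60 (camera adjusted p = 6.3e-05; adjusted p = 0.31 with an estimated correlation). The S14 gene rpsN2 fell from 29.9 ± 2.74 to 2.74 ± 0.654 (log2 change -3.06), rpmI from 228 ± 6.27 to 57.2 ± 11.7 (-1.99), rpsF from 863 ± 36.2 to 276 ± 14.1 (-1.64) and rplL from 70.7 ± 4.71 to 24.1 ± 2.10 (-1.52). In the long cluster OG1RF_10150 to OG1RF_10178, 24 of 29 genes fell and 0 rose. One of the 5 genes that rose, prmA, encodes a methyltransferase that modifies a ribosomal protein. Of 27 genes for aminoacyl-tRNA synthetases, which load amino acids onto transfer RNA, 18 rose and 5 fell, the same adjusted over the list alone (median log2 change 0.63; camera adjusted p = 0.037; adjusted p = 0.69 with an estimated correlation). With library totals 13 were called higher and 6 lower, with a median log2 change of 0.27. Among the list's genes, OG1RF_10760 rose by 1.73, glyS by 1.67, tyrS2 by 1.47 and glyQ by 1.38, while proS fell by 1.44. OG1RF_10760 has the product name of a lysyl-tRNA synthetase, but the list also held lysS (0.11, limma adjusted p = 0.42). The log2 change of lysS turned to -0.03 with upper-quartile scaling and to -0.26 with library totals, and was not called with either. OG1RF_10760 is placed by its product name alone and may not belong there. The camera call of the tRNA synthetases ended without mono-species sample 1 (adjusted p = 0.060), without mono-species sample 3 (0.059), with the replicate number as a block (0.069) and with the filter of 10 CPM (0.087).

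RNA levels of most peptide uptake genes were lower in dual-species biofilms. Of 12 peptide uptake genes, 11 fell and 1 rose, the same adjusted over the list alone, with a median log2 change of -1.06 (camera adjusted p = 0.0042; adjusted p = 0.33 with an estimated correlation). The transporter dtpT fell from 89.1 ± 11.9 to 17.4 ± 2.88 (log2 change -2.30), the binding protein OG1RF_10057 from 29.2 ± 1.46 to 6.33 ± 1.63 (-2.06), opp1C from 143 ± 11.9 to 39.8 ± 5.90 (-1.83) and opp1A from 203 ± 10.5 to 61.2 ± 7.39 (-1.72). The gene that rose was OG1RF_10540, an oligopeptide binding protein (0.62; not called with library totals). Of 19 amino acid uptake genes, 9 fell and 2 rose, the same adjusted over the list alone (camera adjusted p = 0.11). With library totals 13 of them were called lower and 0 higher. Among them glnP fell from 381 ± 22.4 to 83.9 ± 6.95 (log2 change -2.17).

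RNA levels of genes for surface proteins anchored or bound to the cell wall were lower on balance. Of 30 genes on that list, 16 fell and 4 rose, the same adjusted over the list alone, with a median log2 change of -0.56 (camera adjusted p = 0.017; adjusted p = 0.60 with an estimated correlation). One that rose, srtA (0.46, not called with upper-quartile scaling or library totals), encodes an enzyme that anchors some of these proteins. With library totals 2 of the 30 genes were called higher and 25 lower, and with upper-quartile scaling 2 and 19. The WxL domain proteins OG1RF_10450 and OG1RF_10488 fell by 1.84 and 1.09 on the log2 scale, and the anchored proteins ypdD and OG1RF_11924 by 1.23 and 1.04. The collagen adhesin gene ace, OG1RF_10878, fell from 27.3 ± 4.44 to 17.4 ± 1.02 (log2 change -0.61, limma adjusted p = 0.0053). It is not among the 30 genes, because the list's symbols and wording missed it. In the ebp locus, which encodes pili that take part in attachment, 1 of 5 genes fell, 0 rose and 4 were not called, the same adjusted over the list alone (camera adjusted p = 0.79). The gene that fell was OG1RF_10871, from 207 ± 3.76 to 134 ± 24.1 (-0.65). The others were OG1RF_10868 (0.50), OG1RF_10869 (-0.32), OG1RF_10870 (-0.18) and the sortase gene OG1RF_10872 (0.38). Without dual-species sample 1, OG1RF_10868 (0.80), OG1RF_10869 (-0.39) and OG1RF_10872 (0.58) were called, as was OG1RF_10868 without mono-species sample 1 (0.73). With library totals OG1RF_10869 (-0.69) and OG1RF_10870 (-0.56) were called lower, and OG1RF_10869 (-0.46) with upper-quartile scaling.

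Fsr is a quorum sensing system that turns on the secreted proteases gelE and sprE. Of its 5 genes 4 rose and 0 fell, the same adjusted over the list alone, and camera did not call the list (adjusted p = 0.077; 0.042 with library totals and 0.045 without dual-species sample 2). Gelatinase gelE rose from 664 ± 89.5 to 2120 ± 336 (log2 change 1.67), sprE from 1202 ± 146 to 3694 ± 191 (1.62) and the response regulator gene fsrA from 4.43 ± 0.483 to 30.9 ± 10.7 (2.51). The sensor gene fsrC rose from 90.1 ± 6.89 to 142 ± 55.0 (0.59, limma adjusted p = 0.032). That call ended with upper-quartile scaling (log2 change 0.45) and library totals (0.21), and without any one of mono-species samples 1 to 3 (0.53, 0.63 and 0.62) or dual-species sample 3 (0.30). The log2 change of fsrB was 0.16 (adjusted p = 0.31) and -0.21 with library totals.

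**Figure D2:**
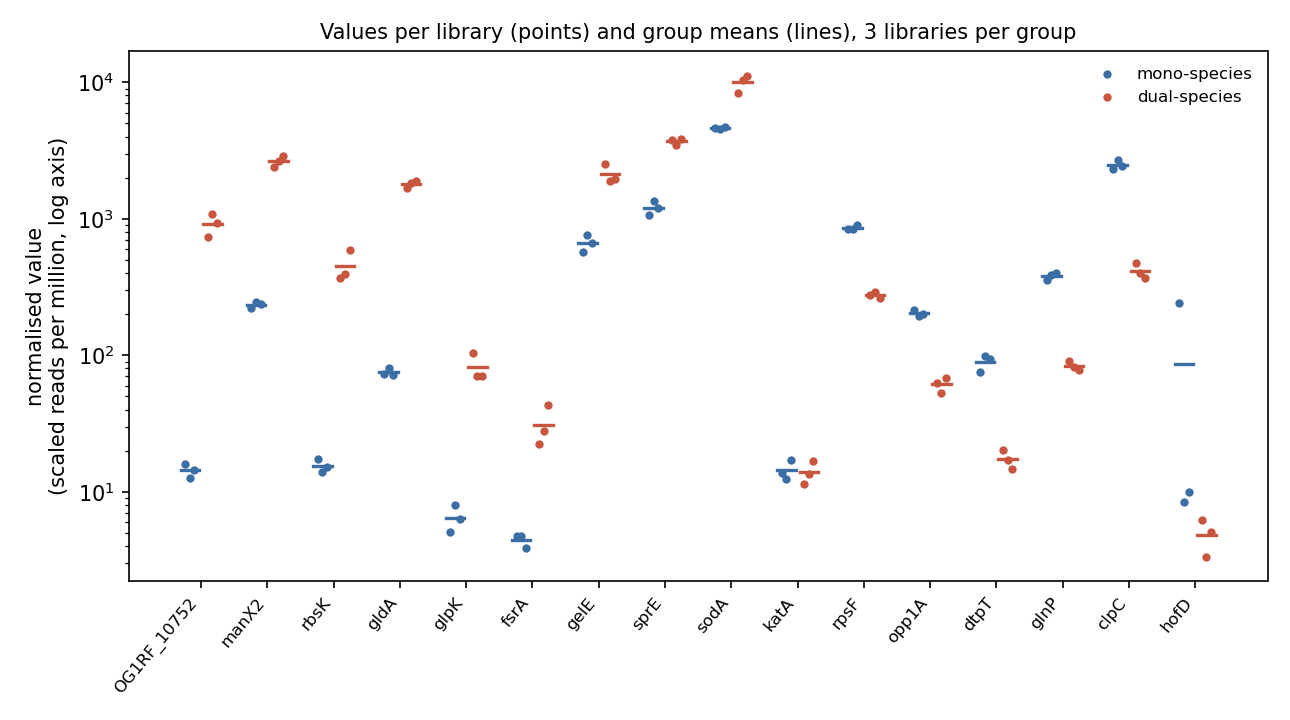
Signal of 16 genes in each library (log axis, scaled CPM); blue points are the 3 mono-species and red points the 3 dual-species libraries, and lines are group means. OG1RF_10752 goes from a mean of 14.3 to 917 and clpC from 2488 to 413, while hofD is high in mono-species sample 1 alone.

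Stress genes went both up and down, and camera called none of their lists. Of 16 chaperone and protease genes, 9 fell and 4 rose (9 and 5 adjusted over the list alone, camera adjusted p = 0.18). With library totals 11 were called lower and 1 higher. The regulators ctsR, from 34.7 ± 6.39 to 6.65 ± 0.774 (log2 change -2.21), and hrcA (-1.84) fell, as did clpE (-1.40), clpP (-1.34) and grpE (-1.50). The protease gene htrA (1.48) rose, as did groEL (0.70) and clpB (0.58), both not called with library totals (0.32 and 0.20). The chaperone dnaK, among the 3 genes with the highest mean signal, went from 35024 ± 1607 to 44603 ± 3687 (0.35, limma adjusted p = 0.052). It was called with median-ratio scaling (0.37), the filter of 10 CPM, the robust step, a pseudocount of 0.1 and voom, and without dual-species sample 1 (0.41), and its log2 change was -0.03 with library totals. Of 28 oxidative stress genes, 10 rose and 6 fell (9 and 6 adjusted over the list alone), with a median log2 change of 0.04 that turned below 0 with upper-quartile scaling and library totals (8 higher and 11 lower with the latter; camera adjusted p = 0.66). Superoxide dismutase sodA rose from 4620 ± 70.6 to 9998 ± 1493 (1.10), the peroxiredoxin ahpC from 423 ± 26.6 to 1015 ± 362 (1.21) and NADH peroxidase npr by 1.69, while trxA and msrB fell by 1.41 and 1.81. Catalase katA had a signal of 14.4 ± 2.40 and 13.9 ± 2.64 (-0.05, limma adjusted p = 0.81), without a detectable difference. Of 12 genes on the Gls24 and general stress list, 6 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.29; the median of 0.25 turned below 0 with library totals, where 4 were called higher and 4 lower), and the Gls24 genes OG1RF_10072 and OG1RF_10071 rose by 2.45 and 1.92.

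Camera called none of the lists for lipid, nucleotide and energy metabolism at the preset correlation. Of 18 fatty acid synthesis genes, 11 fell and 4 rose, the same adjusted over the list alone (camera adjusted p = 0.16); the acetyl-CoA carboxylase gene accD fell by 1.36 on the log2 scale, while fabH, in the same stretch of the gene order, rose by 0.61 (not called with library totals). Of 16 pyrimidine synthesis genes, 9 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.11; 0.032 without dual-species sample 3), with pyrC at 2.16 and carA at 2.04. Of 19 purine synthesis genes, 5 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.92); the median log2 change of 0.19 differed in sign from the mean of -0.03 and turned below 0 with library totals (2 higher and 9 lower). The list for the F-type ATP synthase, which couples proton flow to ATP, held 14 genes, of which 8 rose and 4 fell (camera adjusted p = 0.51); with library totals 3 were called higher and 5 lower, and the median log2 change went from 0.53 to 0.15. It took in 5 genes of the V-type enzyme, and without them 8 of 9 rose and 0 fell (camera adjusted p = 0.032; adjusted p = 0.54 with an estimated correlation), an alternative added after the values were seen. That increase depended on the scaling: in the block OG1RF_11985 to OG1RF_11992, 7 of 8 genes were called higher with the authors' scaling and 2 of 8 with library totals. Of 9 V-type ATPase genes, 5 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.32). That list lacked atpA, OG1RF_11213 (-1.22), and the gene that rose, ntpJ (0.54), lies outside the V-type block. In the block OG1RF_11207 to OG1RF_11215, 6 of 9 genes fell and 0 rose, and 8 of 9 were called lower with library totals. Of 9 arginine deiminase genes, 3 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.66), with arcA at 1.24, arcB at 1.13 and arcC3 at -0.69; the list's median of 0.22 turned below 0 with library totals (3 higher and 4 lower).

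Other genes taken by the rule on size were of several kinds. OG1RF_10855, a GNAT family acetyltransferase, rose from 3.75 ± 0.684 to 65.5 ± 11.7 (log2 change 3.80), and the ABC transporter membrane protein OG1RF_11763 from 3.85 ± 0.399 to 48.6 ± 2.54 (3.36). The major facilitator transporter OG1RF_11672 fell from 575 ± 104 to 71.4 ± 10.6 (-2.99), as did the ABC transporter genes OG1RF_12354 (-2.99) and OG1RF_11131 (-2.30), and the fibronectin-binding protein gene OG1RF_10229 from 113 ± 17.5 to 22.1 ± 3.68 (-2.30). The size of the change of hofD, a prepilin peptidase gene, rested on 1 library: its signal was 241, 8.48 and 9.97 in mono-species samples 1 to 3 and 3.34 to 6.18 in the dual-species samples (log2 change -2.35, limma adjusted p = 0.045). Without mono-species sample 1 its log2 change was -0.83 and still called (adjusted p = 0.0086). The hofD call ended without dual-species sample 2 (adjusted p = 0.13) or 3 (0.070), with the robust step (0.23), with a pseudocount of 5 (0.075) and with voom (0.072).

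**Figure D3:**
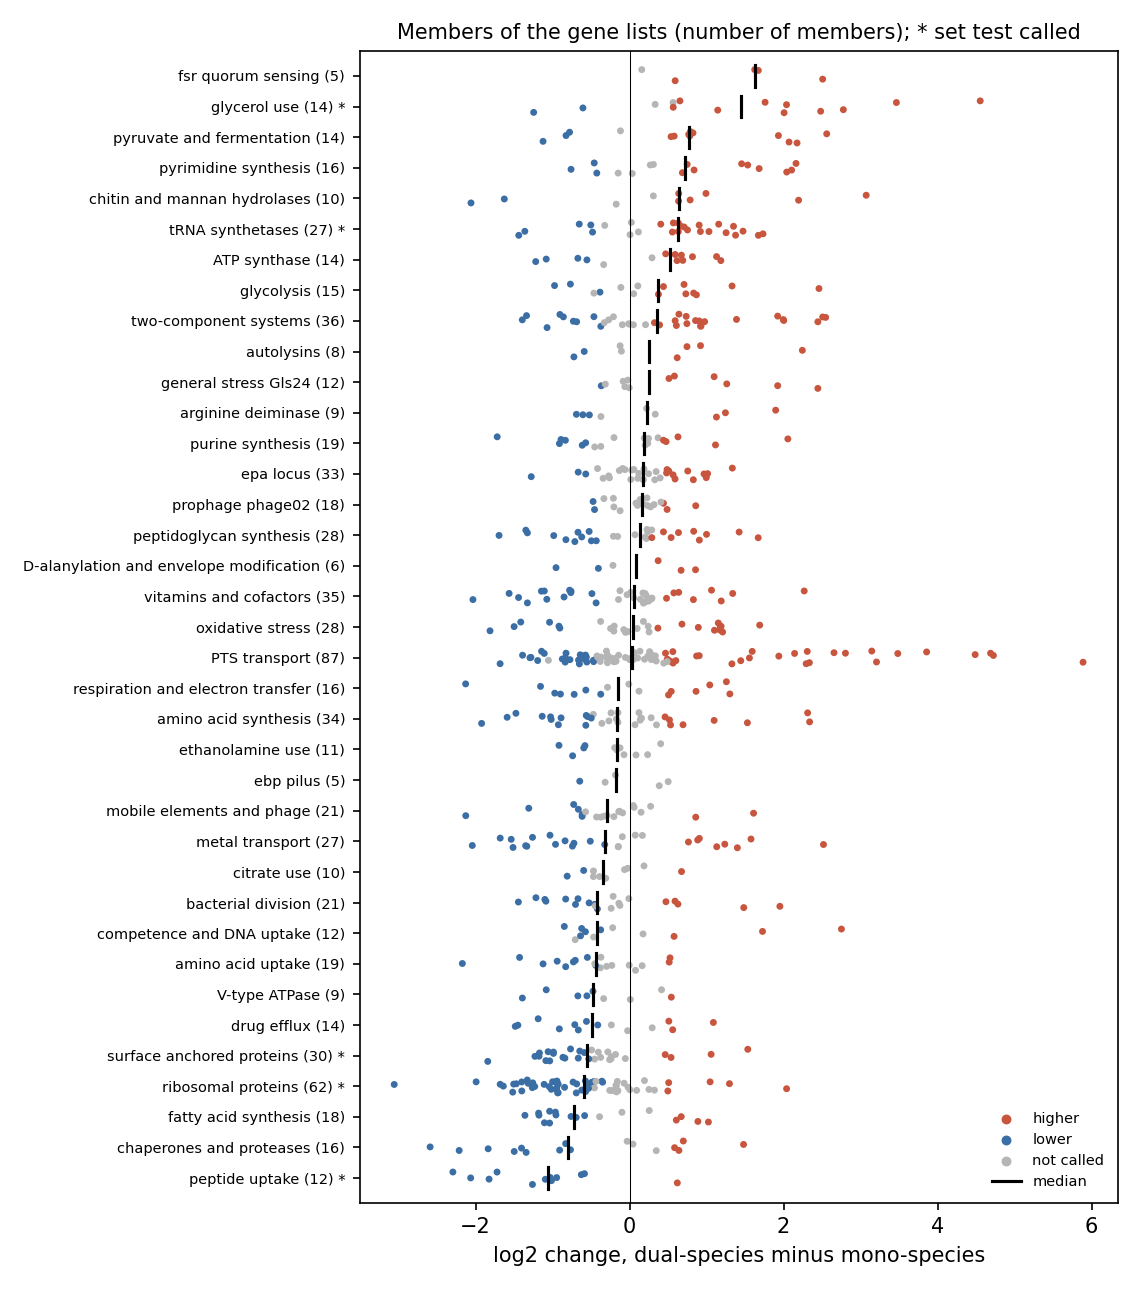
Log2 change, dual-species minus mono-species, of each member of the 37 tested gene lists (points; number of members in brackets); red is called higher, blue called lower, grey not called, and black bars are medians. Lists with a star, such as the 62 ribosomal protein genes and the 12 peptide uptake genes, were called by camera with the preset correlation, and 0 were with an estimated one; several medians near 0 change sign with plain library totals.

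Camera called 5 of the 37 lists at the preset correlation and 0 with the correlation estimated per list, where 3 lists had an unadjusted p under 0.05; fry called 25 as moving one way and 36 as changing in either direction. Splits of the 6 samples that mix the groups gave up to 10 lists by camera. Those splits still hold the group difference in their spread, so they cannot rank list calls against gene calls. The 5 list calls depended on how the correlation between genes was treated.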

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

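The pseudocounts, limma-voom, thinned libraries, treat and lists without stray members were chosen after seeing the data. The count of 1696 called genes stayed within 1.5 times under every alternative run for it: 1685 to 1757 across scalings, 1400 of 1898 tested genes with the filter of 10 CPM, 1334 at an adjusted p under 0.01, 1713 with the robust step, 1702 and 1682 with pseudocounts of 0.1 and 5, 1701 with voom and 1663 with thinned libraries. Of the 1696 genes, 1381 were also called with library totals. Leaving out each library in turn gave 1497 to 1760 genes, 696 to 792 genes at least 2-fold and 4 to 7 lists. The 731 genes at least 2-fold became 322 with limma's treat, a stricter test by its construction; other alternatives gave 560 with a pseudocount of 5 to 856 with voom. The 5 lists called by camera became 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 25 with fry, which does not compare a list with other genes.

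Replicate numbers did not pair the samples: deviations of same-numbered samples from their group means correlated at -0.07, -0.14 and 0.12 across genes, and 2 of 6 libraries correlated best with their own number in the other group. With the number as a block, 1660 genes (831 higher, 829 lower), 735 genes at least 2-fold and 4 lists were called.

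Among alternatives for the 54 named genes, 892 values kept their side of the threshold, 13 gained a call, 11 lost one and 1 reversed. The 892 include changes of direction where neither fit called the gene, such as fsrB (-0.21) and dnaK (-0.03) with library totals. The reversed value was that of gap2, not called with a log2 change of 0.05 but called lower at -0.33 with library totals. Its cause was not tested beyond the shift of all genes. For single lists the numbers were 666 kept, 26 gained and 9 lost. The low-value filter removed no gene, so dropping it tested nothing. Values from edgeR's quasi-likelihood test and glmTreat, and from DESeq2, are not reported. The tables held scaled values, the case for which limma-trend had been set, although the reads could be worked out. In a single trial after the results were seen, edgeR and DESeq2 called about as many genes as limma, and glmTreat more than treat. On simulated reads the edgeR fit of that trial called many unchanged genes. The cause was not looked into and may lie in the trial itself, so the trial gives no verdict on edgeR. Not run was the removal of ribosomal and transfer RNA, which the tables lack. Camera was not run on voom values. Depth limits genes with few reads: in 58 genes a library held fewer than 10.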

Other observations

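The test of a uniform background, the thinned libraries, and the counts of gene blocks and runs were chosen only after results had been seen. The single genes named in this paragraph were picked because they were called, so they say nothing of their pathways as groups. The iron-sulfur assembly genes sufC and sufD rose by 3.22 and 2.52 on the log2 scale. Of the phosphate binding protein genes, pstS2 rose by 2.32 and pstS fell by 1.04, and of the folate genes, folC rose by 2.27 while folP and folE fell by 2.03 and 1.33. Runs of at least 5 neighbouring genes called in 1 direction numbered 66 (32 higher, 34 lower), against a median of 13 and at most 27 in 1000 shuffled gene orders. Shuffling treats neighbours as independent, whereas bacterial neighbours are often transcribed together, so an excess of runs could be foreseen. In addition, luxS (2.31), the division genes ftsZ (1.95) and ftsA (1.48) and the copper transporter gene copB (1.58) rose, and glnA (-1.59), the division gene ftsK (-1.22) and the copper exporter gene actP (-2.04) fell.

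Camera called none of the following lists at the preset correlation, with camera adjusted p from 0.25 to 0.92. Of 36 two-component system genes 19 rose and 9 fell (19 and 10 adjusted over the list alone); the list took in the Gls24 genes OG1RF_10071 and OG1RF_10072, and without them 17 of 34 rose and 9 fell (17 and 10 adjusted over the list alone). Of 27 genes on the metal transport list 8 rose and 14 fell; among the 27 were genes that are not transporters, such as sufD, the serine dehydratase genes sdaA (0.91) and sdaB (-0.74) and the iron-sulfur protein genes OG1RF_10887 (1.40) and OG1RF_11297 (-0.72). Of 21 division genes 5 rose and 10 fell. Of 28 genes on the peptidoglycan synthesis list 9 rose and 11 fell (10 and 11 adjusted over the list alone), and the 28 took in tgt (-0.21, not called), whose product modifies transfer RNA. Of 6 genes for D-alanylation and envelope modification, 3 rose and 2 fell, and of 8 autolysin genes 4 rose and 2 fell. Of 10 chitin and mannan hydrolase genes 6 rose and 2 fell, with the glycoside hydrolase OG1RF_10064 at 3.07 and the family 20 glycosyl hydrolase OG1RF_10107 at 2.19, while map (-2.06) and trePP (-1.63), which act on other sugars, fell. Of 18 phage02 genes 3 rose and 2 fell (2 and 1 adjusted over the list alone), and of 21 mobile element genes 2 rose and 6 fell. Of 12 competence genes 3 rose and 5 fell (3 and 7 adjusted over the list alone), of 16 respiration genes 6 rose and 7 fell, and of 14 drug efflux genes 3 rose and 8 fell. Of 35 vitamin and cofactor genes 8 rose and 13 fell, of 34 amino acid synthesis genes 8 rose and 12 fell, and of 33 genes of the epa cell wall polysaccharide locus 11 rose and 3 fell (9 and 3 adjusted over the list alone). Of 11 ethanolamine genes 0 rose and 4 fell, and of 10 citrate genes 1 rose and 2 fell. Where no second pair of numbers is given, the numbers adjusted over the list alone were the same. The medians of the two-component, autolysin, epa and phage02 lists turned below 0 with library totals, and those of the peptidoglycan, D-alanylation and vitamin lists with upper-quartile scaling as well. With library totals the calls were 14 higher and 14 lower on the two-component list, 6 and 8 on the epa list, 3 and 4 on the autolysin list, 1 and 6 on the phage02 list, 5 and 13 on the peptidoglycan list, 1 and 3 on the D-alanylation list, 5 and 13 on the vitamin list, 4 and 19 on the amino acid synthesis list, 2 and 14 on the mobile element list, 2 and 15 on the division list, 7 and 17 on the metal transport list, 4 and 3 on the hydrolase list, 2 and 7 on the competence list, 4 and 9 on the respiration list, 1 and 10 on the drug efflux list and 0 and 6 on the citrate list. The wording of the lists took in further genes of other kinds, such as the regulator gene ccpA (1.30) on the respiration list. Mean and median differed in sign in the competence, peptidoglycan and vitamin lists.

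The 6 samples allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1696 genes by limma and was the only 1 of 10 with as many; the highest of the other splits gave 0, with 2 to 27 genes at an unadjusted p under 0.05 (1772 in the real split). For genes changed at least 2-fold the real split gave 731 and the highest other 0, again 1 of 10 with as many. Every other split mixes the groups, so the group difference enters its spread and few gene calls could be foreseen. The 0 calls therefore give no measure of chance. For lists called by camera, 7 of 10 splits gave as many as the real 5, and the highest other gave 10.

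Changes in most genes, with a split between higher and lower that moved with the scaling, had 2 technical explanations that were tested. With every library thinned to the reads of the shallowest, 1663 genes were called. That argues against the greater number of reads in the dual-species libraries, by itself, as the whole cause. Thinning cannot test other differences between libraries that went along with depth. Without the 50 most abundant genes in the library totals, 36.9% of called genes were higher, against 30.7% with full totals and 50.4% with the authors' scaling, so those genes were not the whole cause of the difference between scalings. Those genes held 54.6% to 55.6% of reads in mono-species and 57.9% to 59.8% in dual-species libraries. The yeast and the smaller volume of E. faecalis suspension came together, so either could lie behind the changes, and which scaling is right stays open.

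Genes with low signal were lower in dual-species biofilms: the median log2 change was -0.32, -0.33 and -0.24 in the lowest 3 of 10 equal groups of genes by mean signal and 0.34 in the highest. In thinned libraries the median of the lowest 3 groups was -0.30, as at full depth. Random thinning leaves the scaled signal of each gene unchanged on average, so it tests only counting noise. It cannot test other library differences that went along with depth. A uniform low background in the mono-species libraries, such as reads from traces of genomic DNA, would give an equal difference in signal at each level, a ratio of 1 between the third and the first group. The ratio was 3.11 (95% bootstrap interval 1.47 to 5.06), above 1 but below the ratio of 5.21 between their signals. A background that scales with gene length could give such a value, so it stays open, as does a biological difference between the groups.

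Genes near dnaA, which lies near the replication origin, tended to be lower in dual-species biofilms: the Spearman correlation across genes, which are not independent, between log2 change and distance from dnaA in gene order was 0.15. It was 0.14 without the ribosomal protein genes and 0.16 with each change taken relative to the median of its signal group, which argues against both as the whole cause. A lower dose of genes near the origin, as in cells that start replication less often, is a hypothesis that predicts a correlation above 0 on both arms, and the arms gave 0.137 and 0.170. A share of 0.0831 of 2564 rotations of the gene order gave a correlation as large over the whole order. That rotation threshold had been set as excluding the hypothesis, which was wrong, because missing it excludes no small dose difference while both arms lie above 0; the hypothesis stays open.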
